A study of Homo sapiens with 6 samples.

How the data were processed

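RNA from sorted side population (SP) cells and from cells titled non-SP of a Hodgkin lymphoma line was measured on 6 single-colour Agilent expression arrays, with 3 arrays per group. The extract protocol speaks of SP or MP cells, and whether MP and non-SP are the same population was left open. Per the labels' protocols, total RNA was isolated with Trizol, treated with DNase and labelled with Cy3 by a low-input amplification kit. Per the labels, the sample titles and characteristics name the line L428, while the source field names KMH2; the conflict was left open and no sample was assigned to a line from its values. Groups and replicate numbers were taken from the sample titles.

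The deposited scanner files hold the intensity of each spot on a linear scale. Per the file headers, these intensities were extracted with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, and the submitters' processing notes give the version as 10.7. Per the file headers, the processed signal had been background-subtracted, spatially detrended and floored, and the flags for spots well above background, saturated or non-uniform are 0 or 1, and no scaling between arrays is named. The authors' value table of the same arrays is on a log2 scale. Its offset from the log2 processed signal was constant within 0.001 for 99.7 to 99.9% of the 40178 probes compared on each array, and the offset placed it at about the 75th percentile of each array, with no centring of genes. Its column medians were -3.01, -3.04 and -3.07 for SP replicates 1 to 3 and -3.14, -3.00 and -3.13 for non-SP replicates 1 to 3. How that table was made is not given in the sources used here. The table served as an alternative only.

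For the main values, spots marked as non-uniform outliers were set missing, control spots were left out, replicate spots of a probe were averaged, and log2 processed signal was expressed relative to the 75th percentile of the array. Probes were kept when they were well above background on all 3 arrays of at least 1 group and measured on at least 2 arrays of each group. Each gene was represented by the probe with the highest mean signal over the 6 arrays. Gene symbols came from RefSeq accessions in the files, matched without versions to a RefSeq gene table of assembly GRCh38.p14. Of 41000 non-control probes, 26386 matched 1 symbol, 0 matched several and 14614 matched none. Transcripts without a symbol were kept in the test, so 10324 of the 15264 genes tested carry one. The file headers name another genome build than this table, so no coordinates are given. In the gene tables, 64 probes of XIST and of Y-linked genes were left out.

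Differences, always SP minus non-SP, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), with group means as the only terms and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Values are given as mean ± SD, and differences with the standard error (SE) of the fit. Gene lists were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01, for lists with at least 5 tested members. Missing values of a gene were replaced by its mean for the list tests only. All 35 lists, the comparison, the rule for named genes and the other settings listed below were fixed before the data were examined. The named genes were the 12 largest positive and 12 largest negative differences among genes past the threshold whose arrays did not overlap between groups and that carried a symbol. From each list up to 4 members past the threshold were added, or the 2 members with the smallest p where there was none, together with genes chosen beforehand, among them ABCG2, ABCB1, CAT, SOD2, GCLM, HMOX1, TXNIP, FOXO3, NFE2L2, TNFRSF8 and MKI67. For a probe not well above background on any array of a group, the fold is a bound: the mean of the brighter group over the mean, per array, of the higher of the probe's own signal and the lowest signal of any probe well above background. On the common floor, chosen after the data had been seen, all arrays were raised to the highest of these lowest signals.

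The array headers placed SP and non-SP arrays of equal replicate number on the same slide, with 3 slides in all, every SP array at position 1 and every non-SP array at position 2. Slide and replicate number are therefore the same factor, and a fit with the slide as a block was run beside the pooled fit, with differences within each slide. Position on the slide and group cannot be told apart.

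The procedure was tested on simulated data made from the 15042 genes measured on all 6 arrays, with 200 genes changed in each of 5 rounds. With each gene's moderated SD in both groups, limma recovered 0% of genes changed by 0.5 log2 units and 37.6% of those changed by 1. It recovered 88.8% of those changed by 2 and 97.2% of those changed by 4, and 5.25% of its calls were false. With each group's own sample SD, which keeps the larger spread of the SP arrays, 2.8%, 40.8%, 77.2% and 91.6% were recovered and 15.3% of the calls were false. That SD comes from 3 arrays and is itself uncertain, so the 15.3% does not measure the larger spread alone. Camera recovered a shift of 0.4 in a list of 23 genes in 20 of 20 rounds with either spread and called 1 and 3 of 400 unshifted lists. Genes were simulated independently of one another, so this false rate does not cover lists whose members move together. In the real arrays the estimated inter-gene correlation of a list reached 0.71 (metallothioneins). Of the lists that passed with the preset, JAK-STAT targets and MHC class II genes each had an estimate of -0.035, below 0.01. The others that passed had estimates from 0.042 to 0.35. The unadjusted camera p of those 2 lists still rose with the estimate, from 0.00703 to 0.0445 and from 0.00287 to 0.0353. Members moving together therefore do not account for the loss of these 2 calls.

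The other settings were 3 other between-array scalings, normexp background correction with an offset of 50, 2 other filters on dim probes, 2 other ways to treat several probes of a gene, trend and robust variance, array weights, a 2-fold minimum, the replicate block, the authors' value table, outlier spots kept, each array left out in turn, an estimated inter-gene correlation and the fry rotation test. Normexp was planned on the mean spot signal. The median spot signal was used in its place because the files hold that column. The array number limits the precision of every value. No label says that the replicates came from separate cultures or sorts, so p-values measure only the spread between these samples, which may be technical.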

Results

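Gene expression was compared between SP cells and non-SP cells sorted by flow cytometry from a Hodgkin lymphoma cell line, named L428 in the titles and KMH2 in the source field. SP cells are cells that retain little of a DNA dye because they pump it out. The titles name the other group non-SP, while the extract protocol speaks of SP or MP cells, and whether MP and non-SP are the same population is not stated. The study asked why the intracellular concentration of reactive oxygen species is low in SP cells. There were 3 arrays per group, each with 41000 probes. Probes well above background made up 52.7, 41.2 and 46.4% on SP arrays 1 to 3 and 58.9, 50.1 and 52.9% on non-SP arrays 1 to 3. The median SD between arrays of a group was 0.25 log2 units over SP arrays and 0.17 over non-SP arrays. Feature Extraction's own quality summary marked all 3 SP arrays for evaluation and all 3 non-SP arrays as in range.

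Cells of the SP gate had higher signals of single genes such as NFKBIA, TNF, TNFAIP3, EGR2 and IL2RA and of TRIM49, TRIM53AP and TRIM64. They had lower signals of the mitotic genes CDK1 and TOP2A and of the cytokine genes CCL24 and IL27. The gene lists that passed, among them NF-kB targets with 4 of 23 members called, all lost their call with an estimated correlation. Of 15264 genes tested, 105 were higher and 69 lower in SP at an adjusted p under 0.05 in limma, and 86 and 53 of these differed at least 2-fold. All 174 calls had arrays that did not overlap between groups, which held for 28.2% of all tested genes where chance gives 10%. It follows from this lack of overlap that on every slide where they were measured, the 105 lay above and the 69 below the non-SP array. With the slide as a block, 7 genes were higher and 3 lower, and 9 of these were among the 174. Of the 36 named genes past the threshold, TRIM64, PRAMEF8, TRIM49, SLC3A1, MUCL3 and NFASC passed with the block, and the other 30 did not, with blocked adjusted p from 0.0825 to 0.0959. The block on genes well above background on all 6 arrays, an alternative chosen after the data had been seen, kept 21 of the 21 named calls it tested. At an unadjusted p under 0.05 the blocked fit had 1699 higher and 2187 lower genes, against 1291 and 1620 without the block. Leaving out single arrays also moved the counts, to 177 higher and 164 lower without SP array 1, 15 and 27 without SP array 2, 2 and 0 without SP array 3, 6 and 1 without non-SP array 1, 3 and 1 without non-SP array 2, and 8 and 1 without non-SP array 3.

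Members of multigene families led the genes higher in SP. TRIM64, of the tripartite motif family, measured 0.40 ± 0.56 in SP (SD, n = 3) and was not well above background on any non-SP array, a difference of at least 21.5-fold (adjusted p = 0.00455). With all arrays raised to a common floor, chosen after the data had been seen, its bound was lower, at least 6.73-fold (adjusted p = 0.0266). PRAMEF8, of the PRAME family, and TRIM48 passed (both adjusted p = 0.0248) without a well measured non-SP array, but differed by 2.38 and 0.50 on the common floor, where their calls ended (adjusted p = 0.117 and 0.315). For TRIM64 another probe, not tested, differed by 3.82. TRIM49 was well above background on all 6 arrays and rose from 0.73 ± 0.08 to 4.87 ± 0.42 (SD, n = 3), which is 17.6-fold (adjusted p = 0.00455), with differences of 4.13, 4.50 and 3.78 within slides 1 to 3. The pseudogene TRIM53AP measured 2.20 ± 0.11 in SP (SD, n = 2), was well above background on 1 non-SP array, and was higher in SP (adjusted p = 0.0192). These families hold near-identical copies, so the copy that gave the signal is uncertain. Other large increases were those of the pseudogene GRM5P1, 25.4-fold higher (adjusted p = 0.00455), and of SLC3A1, a subunit of an amino acid transporter, higher (adjusted p = 0.00455) with 2 non-SP arrays well above background and by 2.35 on the common floor. CD177, a neutrophil surface protein, A1CF and NFASC passed (adjusted p = 0.0421, 0.0448 and 0.0107) and were not well above background on any non-SP array. On the common floor they differed by 1.14, 0.90 and 0.53 and their calls ended (adjusted p = 0.0752, 0.327 and 0.120). MUCL3 (adjusted p = 0.0310) and CCL3L3, a chemokine gene with near-identical copies (adjusted p = 0.0250), were also higher. Both were well above background on 1 non-SP array, so no fold is given, and the common floor ended the call of MUCL3 (adjusted p = 0.383). TRIM53AP, GRM5P1 and CD177 rested on 2 of the 3 SP arrays.

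Among the genes lower in SP, CCL24, an eosinophil-attracting chemokine, fell from 2.72 ± 0.50 to -0.66 ± 0.92 (SD, n = 3), 10.4-fold (adjusted p = 0.0434; 0.0502 on the common floor, where the call ended), with within-slide differences of -2.05, -3.75 and -4.34. IL27, a cytokine subunit, fell 4.83-fold (adjusted p = 0.0250). CRHR1, a receptor for corticotropin-releasing hormone, was not well above background on any SP array and was at least 5.62-fold higher in non-SP, or at least 3.49-fold on the common floor (adjusted p = 0.0192 and 0.0196). C21orf58, also not well above background on any SP array, passed (adjusted p = 0.0482) but lost its call on the common floor (-1.77, adjusted p = 0.0559). NRN1L, well above background on 2 SP arrays, was 5.65-fold lower in SP, HDDC3 4.61-fold, TBX1 3.27-fold, PIP5K1C 3.25-fold and the pseudogene PIN1P1 2.97-fold. PRAM1 and TNFSF12 were likewise not well above background on any SP array. PRAM1 was at least 2.30-fold higher in non-SP, or at least 1.61-fold on the common floor (adjusted p = 0.0423 and 0.0258), and TNFSF12 passed (adjusted p = 0.0228) but not on the common floor (-0.23, adjusted p = 0.338). For RPL7, a ribosomal protein gene, the tested probe was different by -3.63 log2 units (adjusted p = 0.0250) while its other probe differed by 0.16, so the probes disagree.

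NF-kB target genes were higher in SP as a group, with 4 of 23 tested members past the threshold, 0 lower and 19 not passing, and 9 higher when adjusted over the list alone. The list's median difference was 0.43, its camera adjusted p was 2.92e-09, and the call was lost with an estimated correlation (adjusted p = 0.352). Within slides 1 to 3 the median was 0.43, 0.40 and 0.60. NFKBIA, the inhibitor that NF-kB itself induces, rose from 4.16 ± 0.18 to 5.68 ± 0.15 (SD, n = 3), 2.87-fold (adjusted p = 0.0248). TNFAIP3, a feedback inhibitor of the pathway, was 2.20-fold higher, the cytokine gene TNF 2.03-fold and IER3 1.91-fold, with adjusted p of 0.0482, 0.0341 and 0.0482. With the slide block the list passed (adjusted p = 7.13e-09), while these 4 gene calls ended (each adjusted p = 0.0825) with unchanged differences. With the block on genes well above background on all 6 arrays the 4 passed (each adjusted p = 0.0398).

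**Figure D1:**
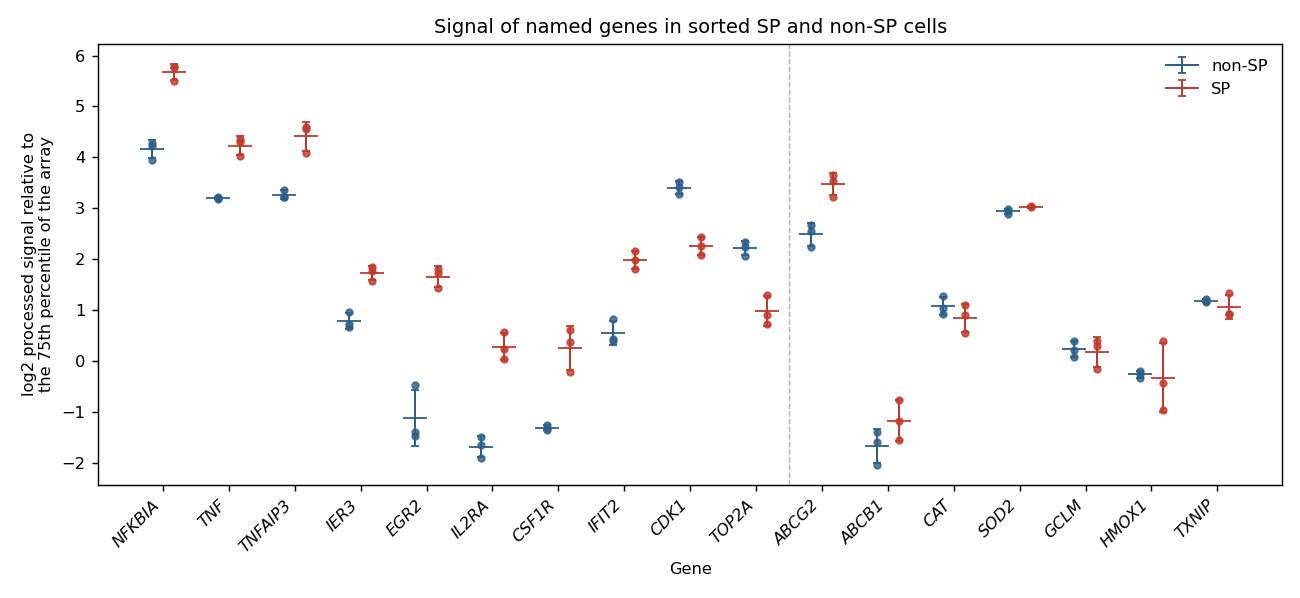
Log2 processed signal relative to the array's 75th percentile (vertical axis) of 17 named genes (horizontal axis) in non-SP cells (blue) and SP cells (red). Points are single arrays, horizontal bars the means and vertical bars 1 SD; genes left of the dashed line passed the threshold and genes right of it did not, and SOD2 has 2 SP arrays.

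Immediate-early genes, which respond within minutes to growth factors and stress, passed the camera test upwards (median 0.49, adjusted p = 0.0152; adjusted p = 0.352 with an estimated correlation). Of 15 tested members, 2 were higher and 13 did not pass, and adjusted over the list alone 6 were higher and 1 lower. The transcription factor gene EGR2 rose 6.84-fold (adjusted p = 0.0248), and within slides 1 to 3 the list's median was 0.42, 0.43 and 0.30. The other call was IER3, which is also on the NF-kB list. The list's call ended with fry (adjusted p = 0.0756) and with no filter on dim probes (adjusted p = 0.236). JAK-STAT target genes also passed upwards (median 0.20, adjusted p = 0.0301; adjusted p = 0.352 with an estimated correlation), with 1 of 16 members higher, 15 not passing, and 2 higher and 2 lower adjusted over the list alone. That member, IL2RA, the alpha chain of the interleukin-2 receptor, rose 3.91-fold (adjusted p = 0.0228). The within-slide medians of this list were 0.17, 0.19 and 0.41, and its call ended without SP array 3 (adjusted p = 0.0654), without non-SP array 3 (adjusted p = 0.0743) and without scaling (adjusted p = 0.0609). It also ended on genes well above background on all 6 arrays without and with the block (adjusted p = 0.0926 and 0.0895), with no filter on dim probes (adjusted p = 0.662) and with the common floor (adjusted p = 0.0653). Markers of Hodgkin and Reed-Sternberg cells passed upwards (median 0.34, adjusted p = 0.0204; adjusted p = 0.352 with an estimated correlation), with 1 of 19 members higher, 18 not passing, and 3 higher adjusted over the list alone. The member was CSF1R, a receptor of macrophage growth factors, which rose 2.95-fold (adjusted p = 0.0427), while TNFRSF8, which encodes CD30, differed by 0.34 ± 0.14 (SE, adjusted p = 0.264). Within slides the medians were 0.07, 0.23 and 0.25, and the call ended with normexp (adjusted p = 0.144), with fry (adjusted p = 0.0756), with no filter on dim probes (adjusted p = 0.596) and with the block on genes well above background on all 6 arrays (adjusted p = 0.0657). Replication-dependent histone genes passed upwards (median 0.19, adjusted p = 0.00213; adjusted p = 0.623 with an estimated correlation) with 0 of 22 members past the threshold over all genes, 8 at an unadjusted p under 0.05 and 7 higher adjusted over the list alone. H2BC12 differed by 1.24 (adjusted p = 0.0561) and H2BC14 by 0.81 (adjusted p = 0.0588), and the within-slide medians were 0.17, 0.31 and 0.29. The histone call ended without scaling (adjusted p = 0.0665), with fry (adjusted p = 0.186) and with no filter on dim probes (adjusted p = 0.244).

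The 2 lists lower in SP were genes of G2 and M phase and of antigen presentation by MHC class II. Of 35 tested G2 and M phase genes, 2 were lower and 33 did not pass, and 5 were lower adjusted over the list alone (median -0.22, camera adjusted p = 0.00961; adjusted p = 0.352 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, fell 2.21-fold (adjusted p = 0.0310), and TOP2A, a topoisomerase of dividing cells, fell 2.35-fold (adjusted p = 0.0463). Without scaling the median of this list was 0.05, under a median of 0.20 over all genes, and its call ended there (adjusted p = 0.0665) and with quantile normalization (adjusted p = 0.0580). MKI67 differed by -0.41 ± 0.17 (SE, adjusted p = 0.261). The within-slide medians were -0.28, -0.21 and -0.16. Of 11 MHC class II genes, 0 passed over all genes, 6 were lower at an unadjusted p under 0.05 and 2 were lower adjusted over the list alone (median -0.34, camera adjusted p = 0.0172; adjusted p = 0.352 with an estimated correlation). HLA-DMB differed by -0.55 (adjusted p = 0.0741) and HLA-DMA by -0.50 (adjusted p = 0.100), with within-slide medians of -0.32, -0.34 and -0.25. The call ended with quantile normalization (adjusted p = 0.0923), without scaling (adjusted p = 0.332) and without SP array 2 (adjusted p = 0.0785).

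**Figure D2:**
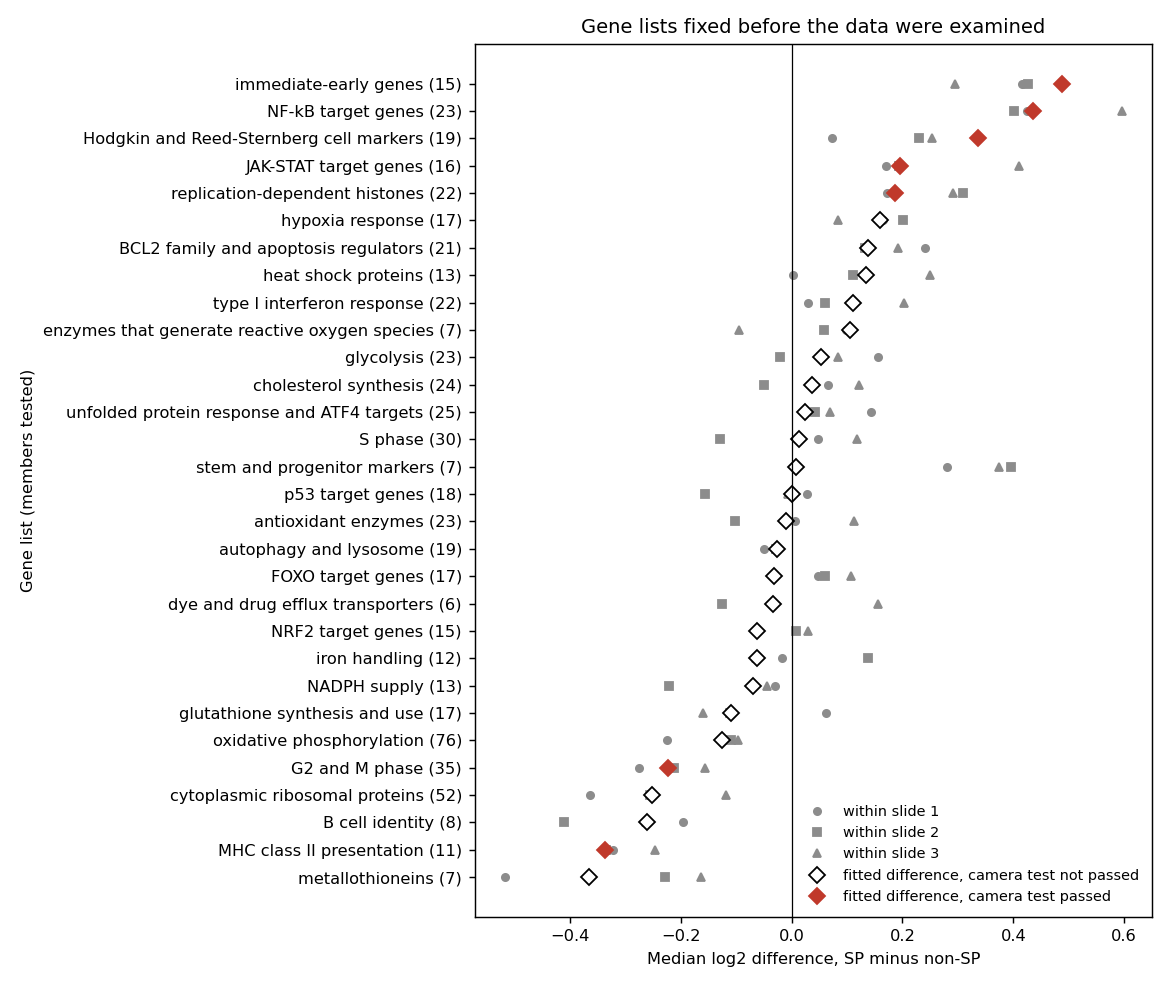
Median log2 difference, SP minus non-SP (horizontal axis), of the 30 gene lists with at least 5 tested members (vertical axis, members in brackets). Diamonds are the fitted differences, filled for the 7 lists that passed the camera test, and grey symbols are the medians within slides 1 to 3; the NF-kB list lies at 0.43 and the G2 and M phase list at -0.22, which was 0.05 without scaling.

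None of the lists bearing most directly on reactive oxygen species passed the camera test, and 0 of their members passed over all genes in limma. In the simulation limma recovered 0 or 2.8% of genes changed by 0.5 log2 units, depending on the spread. Members that differed by 0.5 or less could therefore hardly pass, and their lack of calls does not show equal expression. Without scaling the medians of these lists lay above 0, from 0.16 to 0.38, and the antioxidant list was also above 0 with quantile normalization (0.12) and with scaling to the median (0.02), as was the FOXO list with quantile normalization (0.015). The medians were -0.01 for 23 antioxidant enzymes (camera adjusted p = 0.627), -0.06 for 15 NRF2 target genes (adjusted p = 0.836), -0.11 for 17 genes of glutathione synthesis and use (adjusted p = 0.627), 0.11 for 7 enzymes that generate reactive oxygen species (adjusted p = 0.627), -0.03 for 17 FOXO target genes (adjusted p = 0.219) and -0.07 for 13 genes of NADPH supply (adjusted p = 0.355). For the antioxidant, NRF2 and FOXO lists the camera direction was upwards against a median below 0. At an unadjusted p under 0.05 these lists had 2, 2, 1, 2, 5 and 0 higher members, and 2, 1, 0, 1, 1 and 2 lower ones. Adjusted over the list alone, 1 antioxidant enzyme, 3 FOXO target genes and 2 generating enzymes were higher, and 1 generating enzyme was lower. SESN1 was that antioxidant member and also 1 of the 3 FOXO genes. CAT, which encodes catalase, differed by -0.23 ± 0.19 (SE, adjusted p = 0.544), SOD2 by 0.09 ± 0.13 (adjusted p = 0.764), GCLM by -0.05 ± 0.19 (adjusted p = 0.902), HMOX1 by -0.06 ± 0.33 (adjusted p = 0.941) and TXNIP by -0.13 ± 0.15 (adjusted p = 0.696). The signs of CAT, GCLM, HMOX1, TXNIP and GCLC turned without scaling between arrays, where the median of all genes moved from -0.07 to 0.20. NFE2L2, which encodes NRF2, differed by 0.34 ± 0.15 (SE, adjusted p = 0.295) and FOXO3 by 0.82 ± 0.26 (adjusted p = 0.174). The members with the smallest p included SESN1, with a difference of 1.11 (adjusted p = 0.0623), GABARAPL1 with 1.48 (adjusted p = 0.0614), TXNRD1 with 0.69, MSRA with -0.38, MAOA with 0.53, NCF4 with -0.72, SLC7A11 with 0.78, GCLC with -0.27, TALDO1 with -0.35 and NNT with -0.36.

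Transporters that pump out dyes and drugs did not pass as a list (6 tested, median -0.03, camera direction upwards, adjusted p = 0.627), and 0 members passed over all genes in limma, with 1 higher and 1 lower at an unadjusted p under 0.05. Without scaling the median of this list was 0.24. ABCG2, a transporter known to pump out the dye that defines side populations, measured 3.48 ± 0.22 in SP and 2.49 ± 0.23 in non-SP (SD, n = 3), 1.98-fold higher on average and higher on all 3 slides by 0.99, 0.97 and 1.00, with an adjusted p of 0.0621 that missed the threshold. It was higher adjusted over the list alone. Over all genes it passed under 7 of 20 other settings, with adjusted p from 0.0308 (quantile normalization) to 1.00, not counting the array-weights fit, which stopped before convergence. ABCB1 differed by 0.50 ± 0.26 (SE, adjusted p = 0.357) and ABCC5 by -0.61.

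Among the remaining lists, 2 of 22 type I interferon genes were higher, IFIT2 2.70-fold (adjusted p = 0.0293) and IFI44 2.11-fold (adjusted p = 0.0357), while the list did not pass (median 0.11, adjusted p = 0.177) and had 5 higher and 2 lower members adjusted over the list alone. ATF3, a stress-induced transcription factor, was 2.19-fold higher (adjusted p = 0.0308) and was the 1 call among 25 unfolded protein response and ATF4 target genes (median 0.02, adjusted p = 0.267). With quantile normalization this list passed upwards (median 0.25, adjusted p = 0.0384), as did the glycolysis list (median 0.21, adjusted p = 0.0384). Ribosomal protein genes had a median of -0.25 (52 tested, adjusted p = 0.113), oxidative phosphorylation genes -0.13 (76 tested, adjusted p = 0.177) and metallothioneins -0.37 (7 tested, adjusted p = 0.227). RPL7 was the 1 ribosomal call, also adjusted over the list alone, and 0 members of the other 2 lists passed in limma, with 4 and 1 lower at an unadjusted p under 0.05. With quantile normalization the medians of the ribosomal and oxidative phosphorylation lists were 0.036 and 0.059, and without scaling 0.024 and 0.14. These 3 lists passed downwards with the slide block, at adjusted p of 0.000141, 0.0405 and 0.0405. They also passed downwards with that block on genes well above background on all 6 arrays, with normexp and with no filter on dim probes. Camera compares a list with the other genes. With no filter the median of all genes was 0.20, against -0.07 in the main fit, while the medians of these 3 lists were unchanged. That pass is therefore no separate sign of a fall in these lists. Of 10 groups of spots by mean signal, the brightest had a median difference of -0.14. Whether these 3 lists follow that offset was not tested. The ribosomal list passed too on genes well above background on all 6 arrays, with every probe, with the mean of probes and without SP array 2 or non-SP array 1, and metallothioneins without SP array 2. Without SP array 1 the ribosomal median was 0.053 and the test's direction turned upwards (adjusted p = 0.773). With an estimated correlation and no block their adjusted p was 0.795, 0.703 and 0.703. Lists with 0 members past the threshold over all genes that did not pass camera were B cell identity (median -0.26), hypoxia response (0.16), BCL2 family (0.14), heat shock proteins (0.14), glycolysis (0.05), cholesterol synthesis (0.04), S phase (0.01), stem and progenitor markers (0.01), p53 target genes (0.00), autophagy and lysosome (-0.03) and iron handling (-0.06), with adjusted p from 0.113 to 0.861. For autophagy and iron handling the camera direction was upwards against a median below 0, and without scaling the medians of these 2 lists (both 0.21) and of B cell identity (0.014) were above 0. Without SP array 1 the heat shock list passed (adjusted p = 0.0267), and the interferon list passed too. Adjusted over the list alone, 3 stem and progenitor markers, 2 p53 target genes, 1 BCL2 family gene and 1 autophagy gene were higher. SESN1 was among these p53 genes and GABARAPL1 was the autophagy gene, both already counted among the FOXO targets. At an unadjusted p under 0.05 in limma these lists had from 0 to 5 higher and from 0 to 3 lower members.

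Markers of other cell types were tested in too few members for camera, and 0 passed the threshold in limma. Adjusted over the list alone 1 myeloid marker was higher and 1 erythroid marker lower, the same numbers as at an unadjusted p under 0.05, where 1 T and NK cell marker was lower too. The median was 0.00 over 4 T and NK cell markers, -0.01 over 2 myeloid markers, -0.37 over 4 erythroid markers and -0.21 over 3 stromal markers. CD68 differed by 0.62 (adjusted p = 0.0705), CD4 by -0.57, GZMB by 0.50 and HBD by -0.62. Mitochondrially encoded transcripts had 0 members matched by symbol on the array.

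Dim probes differed between the groups' arrays. After scaling, negative control spots had a mean of -5.11 over SP arrays and -6.09 over non-SP arrays, a difference of 0.98, and probes not well above background on any array differed by 0.87. In 10 groups of spots by mean signal, the 4 dimmest had median differences from 0.36 to 0.93 and the other 6 from -0.14 to -0.0058.

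**Figure D3:**
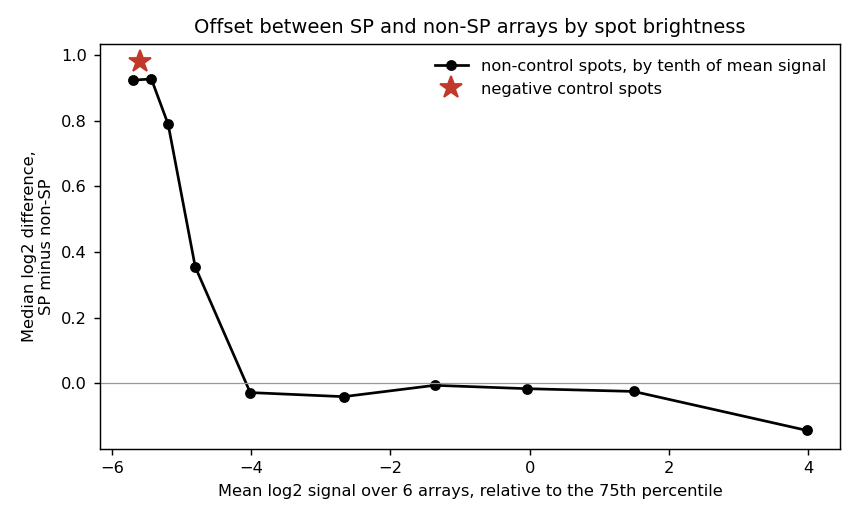
Median log2 difference, SP minus non-SP (vertical axis), against mean log2 signal relative to the array's 75th percentile (horizontal axis), for non-control spots in 10 groups by mean signal (black) and for negative control spots (red star). The dimmest group lies at 0.92 and the brightest at -0.14.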

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

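The common floor, the blocked fit restricted to probes well above background on all 6 arrays and the sign comparison were chosen after the data had been seen. The log2 differences of the 174 calls kept their sign in every fit in which they were tested, but the number of calls depended on the setting. Against 105 higher and 69 lower genes, there were 205 and 122 with quantile normalization, 185 and 93 with scaling to the median, 29 and 14 without scaling, 60 and 66 with normexp, 199 and 106 among genes well above background on all 6 arrays, 165 and 105 with trend and robust variance, and 276 and 228 with a common floor for dim probes. Array weights gave 1323 and 1642, from an estimate that stopped before convergence with weights from 0.236 to 10.96. With no filter on dim probes limma called 0 and 0 of 31727 genes, with 2429 higher and 1155 lower at an unadjusted p under 0.05 and a median of all genes of 0.20. The same-numbered arrays shared a slide, but their deviations from the group means correlated at 0.41, 0.30 and 0.06, and SP array 3 correlated best with non-SP array 2. The replicate block gave 7 and 3 calls, and 276 and 181 when only genes well above background on all 6 arrays were tested. Other settings stayed within 1.5 times of both counts. The share of higher calls was 60.3% by the chosen settings and 47.6% with normexp. Leaving out 1 array gave 2 to 177 higher genes, 0 to 164 lower genes and 6 to 9 lists. The number of lists passing, 7 in the main test, was 3 without scaling, 0 with an estimated correlation and 4 with fry, which asks whether a list moves without comparing it with other genes. Every other setting with a list test gave 6 to 10 lists, and the NF-kB list passed in each list test run except that with the estimated correlation. The test's direction turned in 51 combinations of a result and a setting, 37 of a list and 14 of a gene, and 0 of these had passed the threshold in either fit. Under quantile normalization these were ribosomal proteins (0.036) and oxidative phosphorylation (0.059). Without scaling they were GCLC (0.0027), THY1 (0.069), CAT (0.043), GCLM (0.22), HMOX1 (0.21) and TXNIP (0.15). With normexp they were autophagy (-0.045), iron handling (-0.034), NRF2 targets (-0.023), S phase (-0.00982) and HMOX1 (0.00862). Without a filter they were antioxidant enzymes (0.037), autophagy (-0.042), BCL2 family (0.14), cholesterol synthesis (0.054), glycolysis (0.060), iron handling (-0.063), p53 targets (0.0014), S phase (0.030) and the unfolded protein response (0.024). On all 6 arrays they were antioxidant enzymes (-0.012), NRF2 targets (-0.082), p53 targets (-0.14) and S phase (-0.0024), and the replicate block on those genes turned the same lists except S phase. By the mean of probes it was autophagy (-0.055), and with every probe autophagy (-0.081), NRF2 targets (-0.12) and S phase (-0.020). With array weights they were CAT (0.019) and GCLM (0.091), and with the authors' values and with outlier spots kept SOD2 (-0.30). With fry they were autophagy (-0.026), NRF2 targets (-0.062) and S phase (0.014), and with the common floor NRF2 targets (-0.062). Leaving out 1 array, GCLM ranged from -0.16 to 0.11, HMOX1 from -0.42 to 0.25, NRF2 targets from -0.13 to 0.035, S phase from -0.023 to 0.057, autophagy from -0.12 to 0.0083, ribosomal proteins from -0.47 to 0.053, glutathione genes from -0.15 to -0.072 and iron handling from -0.11 to 0.058. Apart from the test's direction, a list's median changed sign in 75 of 658 combinations, and 1 of these, G2 and M phase without scaling, concerned a list past the threshold. Of the 36 named genes past the threshold, 6 kept their call with the replicate block, 21 of 21 tested with that block on all 6 arrays, 27 on the common floor and 17 without scaling, and 33, 12, 2, 3, 3 and 7 kept it without SP arrays 1 to 3 and non-SP arrays 1 to 3 in turn. The cause was not tested. The number of probes well above background ranged from 16910 to 24133, and for genes under it in 1 group the size of a difference is a bound only.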

Other observations

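The gene list tests, their settings without single arrays and on genes well above background on all 6 arrays, and the counts of other splits were planned, while the cleavage-stage, common floor, other cell type, control spot and single spot tests, and the use of the planned ones to test explanations, were chosen after the values had been seen.

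The genes highest in SP included TRIM48, TRIM49, TRIM53AP, TRIM64 and PRAMEF8, families whose members are active in the cleavage-stage embryo and respond to the transcription factor DUX4. A list of 37 further genes of that kind was written from general knowledge before their values were looked at, and 16 were on the array. Most of these lay near background, so the sizes of their differences depend on the floor. Their median difference was 1.05, and 8 exceeded the offset of 0.98 between the groups' negative control spots. The 2 members well above background on all 6 arrays differed little, HNRNPCL1 by 0.32 (other probe -0.10) and ALPG by 0.0025 (other probe 1.46), and RFPL4B differed by -0.54. LEUTX was well above background on 2 SP arrays and ZSCAN4 on 1, and both on 0 non-SP arrays. TRIM43 was well above background on 3 SP and 2 non-SP arrays, with an SD of 2.98 over SP arrays.

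TRIM49, TRIM53AP and TRIM64 were grouped because their calls held on the common floor, so that outcome is no separate support. Each gene's own difference there still bears on the floor. It exceeded the negative control offset by 3.16, 3.57 and 1.77 in turn. These values argue against the higher signal floor of the SP arrays for these 3 genes. For TRIM48 the floor stays open, as its call ended on the common floor. PRAMEF8 measured -0.98, 1.31 and -0.24 on SP arrays 1 to 3, all above that floor of -2.35. With an SD of 1.17 its call ended there too, so it was not settled. Less the negative control offset, the differences there were -0.48 for TRIM48 and 1.40 for PRAMEF8. Median negative control spots, from -6.75 to -4.43, lay below the common floor on every array. Subtracting their offset is thus a strict measure there, and -0.48 does not mean lower in SP. A wider cleavage-stage programme in SP cells stays open as a hypothesis: the 16 members not seen beforehand lay at percentile 99.98 of 10000 random lists matched on mean signal, but most sat near the floor. Cross-hybridisation among near-identical TRIM and PRAMEF copies stays open for the same reason (percentile 97.11 for the 11 members outside both families), and no probe sequence was searched. Position on the slide was the same for all SP arrays and cannot be told apart from the sorted population, which remains the untested biological explanation.

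The rise of NF-kB target genes may reflect the SP cells themselves or their handling. The tables argue against the signal floor, as the list's median was 0.42 on genes well above background on all 6 arrays. T or myeloid cells in the SP gate would bring their abundant transcripts. LYZ, S100A9, CD3D and S100A8 differed by 1.12, 0.97, 0.93 and -0.06, beside the offset of 0.98 in negative control spots. These transcripts, chosen after the values had been seen, were well above background on 0 SP arrays. This goes against a large share of such cells but cannot exclude a small one. The myeloid marker CD68 went the other way, with a difference of 0.62 (adjusted p = 0.0705 over all genes and 0.00404 over the list alone). NK cells stay open, as GZMB differed by 0.50 and NKG7 by -0.25 and they were well above background on 6 and 5 arrays. CSF1R, known from myeloid cells but not on those lists, was higher in SP, as was CD177, whose call ended on the common floor (adjusted p = 0.0752). Stress of dye loading and sorting stays open, because immediate-early genes passed, though not with an estimated correlation (adjusted p = 0.352) or fry (adjusted p = 0.0756), heat shock proteins did not (camera adjusted p = 0.273) but did without SP array 1 (adjusted p = 0.0267), and no unsorted sample was analysed here.

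Dim probes were higher on SP arrays. Probes not well above background on any array differed by 0.87, and negative control spots, which have no target, differed by 0.98. The median local background was 20, 19 and 18 on SP arrays and 21, 20 and 19 on non-SP arrays. The background-subtracted mean of negative control spots was -4.93, -3.19 and -4.17 on SP arrays and -2.73, -2.42 and -2.64 on non-SP arrays. These values argue against a higher local background on SP arrays, and the source of the offset in the processed signal was not tested. Dim probes did not exceed the control spots (-0.11). Probes well above background on any array were left out of this comparison, so it cannot show whether more genes were weakly transcribed in SP cells. Replicate spots within an array had a median SD of 0.15, 0.12 and 0.14 on SP arrays and 0.09, 0.08 and 0.07 on non-SP arrays, over 119 bright probes. Single spots more than 4 log2 units below all other arrays numbered 34, 18 and 16 on SP arrays and 0 on each non-SP array.

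With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split called 174 genes and the highest of the others 0, and it passed 7 lists against at most 5 in the others, so that 1 of the 10 splits, the real one, reached each real value. Each other split mixed SP and non-SP arrays in both groups, so a difference between SP and non-SP arrays widened the spread there and lowered its calls. At an unadjusted p under 0.05 in limma the real split had 2911 genes and the others up to 1583.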
